A study of Bos taurus with 9 samples.

How the data were processed

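The data are RNA sequencing libraries from polyadenylated RNA of bovine blastocysts, 9 in all and 3 in each of the groups CTR, Nanuq and Cryotop. Per the labels' protocols, pools of 5 to 10 embryos were lysed and RNA was isolated on columns made for very small samples (PicoPure). Libraries were made with the NEBNext Ultra II kit and sequenced on an Illumina instrument to at least 10M reads each. Per the submitters' processing notes, the tools used were Trim Galore 0.6.0, FastQC, STAR 2.7.0e and DESeq2 1.26.0, with the genome build ARS-UCD1.2. The counting tool, gene annotation and strand setting are not given in the sources used here. If strand was not used, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical gene copies may have been split or dropped. Amplified reads without molecular identifiers are not independent molecules, so limits based on counts cover counting error only.

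The authors deposited a table of raw counts per gene, not normalized, with 27607 Ensembl bovine gene identifiers as rows and 1 column per library. Each column was matched to its sample by its name, and 0 columns were left unused. No row lacks a gene identifier. The table holds no symbols. The gene table used here (37063 genes, assembly ARS-UCD2.0) has 0 entries in its Ensembl column, so 0 identifiers were matched to a symbol. For that reason the 31 gene lists fixed before the data were examined (among them pluripotency, trophectoderm, heat shock and other cell types) were not tested, and neither were the covariate for embryo sex and the check of sex-linked genes.

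Total counts ran from 3970666 in Cryotop replicate 1 to 25745731 in CTR replicate 2. Genes were kept by edgeR's filterByExpr, which left 14005. Library sizes were scaled by the trimmed mean of M-values (TMM). Dispersions were estimated over all 9 libraries with 6 residual degrees of freedom. The common dispersion was 0.265, a biological coefficient of variation of 51.5%. The test was edgeR's quasi-likelihood F test with robust estimation, with p-values adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Contrasts were Cryotop against CTR, Nanuq against CTR, Nanuq against Cryotop, the mean of both cooled groups against CTR, and any difference among the 3 groups. The groups, contrasts, tests and most alternatives were chosen before the data were examined. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1 were used. Log2 CPM values used a prior count of 2. Standard errors of log2 fold changes were taken from the fold change and its F value.

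The rule set for naming genes required symbols and so named none. In its place, after the table had been seen, the 2 genes higher and the 2 genes lower with the smallest p-values were taken for each of the 3 pairs of groups. Abundance classes were set at means of 5 and 50 CPM over all 9 libraries. To compare detection at equal depth, the expected number of genes with at least 1 count was computed for a random draw of 3970666 counts from each library. Separation of the groups was tested by a pseudo-F on Euclidean distances of log2 CPM over all 280 splits. For the 2 comparisons that share CTR, counts were simulated 20 times from a single mean per gene with the estimated dispersions.

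The tests were tested on simulated data with 200 changed genes among 14005, 3 times per pair of groups. Counts were drawn with the dispersions edgeR had estimated, the same in all 3 groups. DESeq2 was run there on these 14005 genes, not on the whole table. The shares below hold for that setting. For Cryotop against CTR, edgeR found 30.8% of genes changed 2-fold, and 81.0% of those at 50 CPM or more. At 4-fold it found 58.1% and 100%, and at 1.5-fold 7.46% and 19.7%. For Nanuq against CTR the shares at 50 CPM or more were 76.0% at 2-fold and 23.3% at 1.5-fold, and for Nanuq against Cryotop 68.5% and 14.8%. Of edgeR's calls, 6.80%, 7.69% and 7.77% were false for these 3 comparisons in that order. Of DESeq2's calls, 29.5%, 32.9% and 28.9% were false. DESeq2 also found more of the changed genes at 50 CPM or more: 82.5%, 94% and 79.6% at 2-fold and 30.3%, 46.7% and 26.2% at 1.5-fold, in the same order.

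Alternatives were other scalings (DESeq2-style size factors, library size alone), no filter or a mean of at least 5 CPM, DESeq2, limma voom, no robust estimation, a threshold of 0.1, a fold minimum, the replicate number as a block, fits of 6 libraries, and each library left out. Added after seeing the data were limma voom with library quality weights, counts thinned to the smallest total, a mean of at least 50 CPM, and leaving out both Cryotop replicates 1 and 3. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom of their counts was 21.4 or more.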

Results

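Gene expression was measured by RNA sequencing in hatched bovine blastocysts, embryos that hold a fluid-filled cavity and have left their zona pellucida. The study concerns vitrification, which is cooling to a glass without ice, and how embryos fare after warming. Libraries fell into 3 groups of 3: a control (CTR) and 2 groups named after cooling devices, Nanuq and Cryotop. The design names a standard and an ultrafast cooling group, and the labels do not say which device gave which. Whether the control embryos were cooled is not given in the sources used here. The design describes the pools of all 3 groups as collected after thaw, so a contrast with CTR is one with the control as labelled, not with embryos known to be uncooled. Each library came from a pool of 5 to 10 embryos that hatched within 24 h of thawing, so the transcripts describe embryos that had survived and hatched. Whether the 3 pools of a group came from separate embryo productions is not given in the sources used here, so p-values measure the spread between these pools, which may be partly technical.

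Total counts were 19608058, 25745731 and 19490838 in CTR replicates 1, 2 and 3, and 20813599, 22529555 and 17591464 in Nanuq replicates 1, 2 and 3. In Cryotop they were 3970666, 20253721 and 16343398, so Cryotop replicate 1 held the fewest counts of the 9 libraries. Of 27607 genes in the table, 8824 had no count in any library and 14005 were abundant enough to test. The tested genes held 99.9% of all counts. Of these, 4031 averaged 50 CPM or more (CPM is the count scaled to a common library total), 5821 averaged 5 to 50 CPM and 4153 averaged under 5 CPM. Genes carry Ensembl identifiers only. The files do not pair them with symbols, so the genes below are given by identifier and no function is stated for them.

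Fewer genes were detected in 2 of the 3 Cryotop pools. Genes with at least 1 count numbered 14763 ± 1368 in CTR, 14533 ± 382 in Nanuq and 13371 ± 1751 in Cryotop (mean ± SD, n = 3 each). Cryotop replicates 1 and 3 had 12104 and 12641 such genes, and Cryotop replicate 2 had 15369. With each library reduced to the 3970666 counts of the smallest, the expected numbers were 12104 in Cryotop replicate 1 and 12409 in Cryotop replicate 3. The other 7 libraries then lay between 13577 in CTR replicate 1 and 15002 in CTR replicate 2. Moderately expressed genes were among those missing. Of the genes averaging 5 CPM or more in the other 8 libraries, 126 had 0 counts in Cryotop replicate 1 and 64 in Cryotop replicate 3, against 6 in CTR replicate 1, 4 in CTR replicate 3 and 0 in each of the other 5. A count of 0 allows up to 0.756 CPM in Cryotop replicate 1 and 0.184 CPM in Cryotop replicate 3, where 3 counts are taken as the limit. These limits use totals without TMM scaling and cover counting error only.

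**Figure D1:**
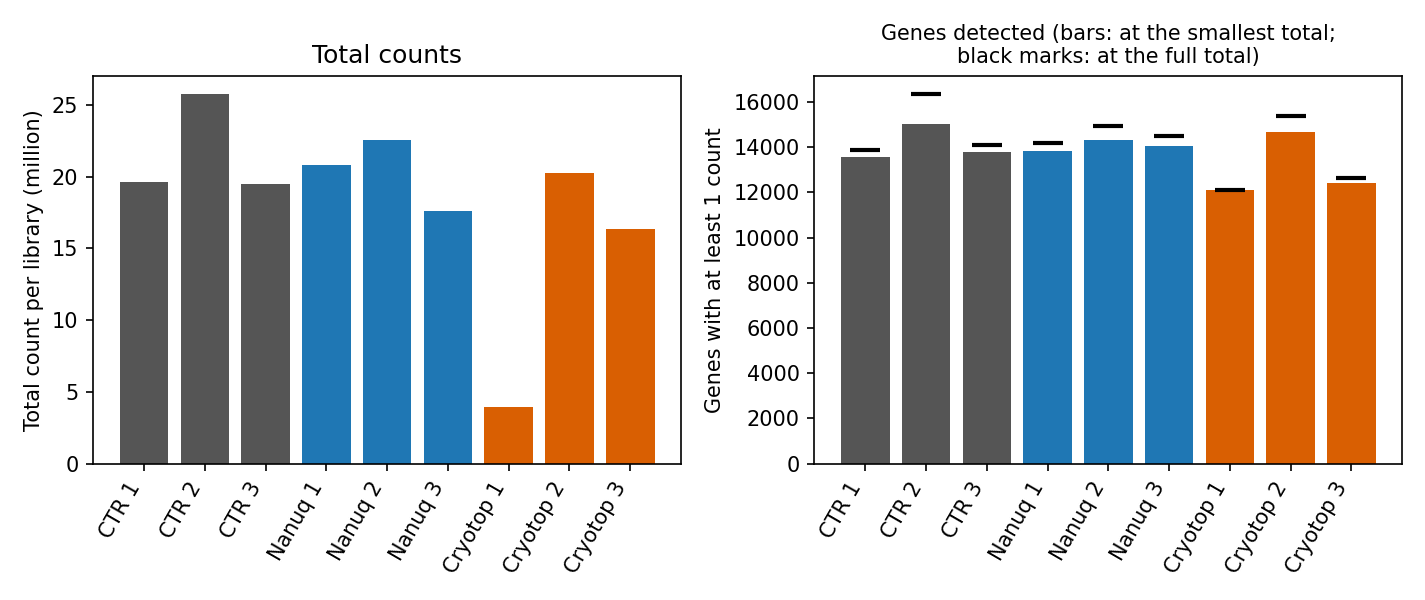
Left, total counts per library; right, the number of genes with at least 1 count, with bars for the number expected at the smallest library's total and black marks for the number at the full total. Colours mark CTR (grey), Nanuq (blue) and Cryotop (orange). Cryotop replicates 1 and 3 have 12104 and 12409 genes at the common total, below the 13577 to 15002 of the other 7 libraries.

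One transcript set Cryotop replicate 1 apart. ENSBTAG00000052217 made up 4.56% of its counts, or 45612 CPM without TMM scaling. The same gene made up 0.381% of counts in CTR replicate 3 and between 0.010% and 0.0864% in the other 7 libraries. The most abundant gene in each of the 8 other libraries was ENSBTAG00000000836, at 1.35% to 1.60% of counts. Both genes are named because they led a library, a choice made after their values were seen.

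Distances between whole transcriptomes did not separate the 3 groups beyond the spread between libraries. Spearman correlations of log2 CPM over the tested genes were 0.966 to 0.970 between CTR libraries, 0.969 to 0.978 between Nanuq libraries and 0.926 to 0.957 between Cryotop libraries. Between groups they were 0.965 to 0.978 for CTR with Nanuq, 0.940 to 0.976 for CTR with Cryotop and 0.942 to 0.980 for Nanuq with Cryotop. These correlations are across genes, which are not independent replicates. The first principal component held 29.1% of the variance and set Cryotop replicate 1 apart, and the second held 23.1% and set Cryotop replicate 3 apart. Distances between groups relative to those within them gave a pseudo-F of 1.05. Against all 280 splits of the 9 libraries into 3 groups of 3, this gave a one-sided exact permutation p of 0.193. For single pairs of groups the exact permutation p was 0.3 for Cryotop against CTR, 0.2 for Nanuq against CTR and 0.4 for Nanuq against Cryotop. With 3 libraries against 3 it cannot go below 0.1.

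**Figure D2:**
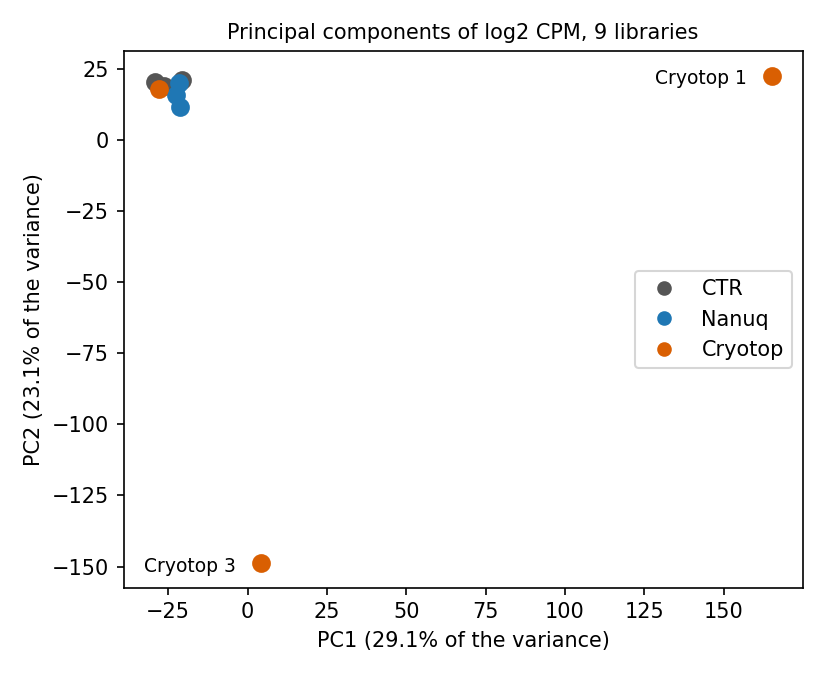
First and second principal components of log2 CPM over the 14005 tested genes, with the percent of variance each holds on its axis. Each point is a library, coloured by group. Cryotop replicates 1 and 3 lie apart from the rest and from each other, and the other 7 libraries lie together.

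The comparison of Cryotop with CTR asks how hatched blastocysts of that device group differ from the control. The gene with the smallest p-value was ENSBTAG00000015792, at 37.9 ± 14.2 CPM in CTR and 101 ± 13.8 CPM in Cryotop (mean ± SD, n = 3), a log2 fold change of 1.41 ± 0.286 (SE). ENSBTAG00000003825 measured 76.6 ± 15.0 CPM in CTR and 128 ± 5.31 CPM in Cryotop, a log2 fold change of 0.74 ± 0.174. Among genes lower in Cryotop, ENSBTAG00000010992 went from 221 ± 15.6 to 129 ± 11.9 CPM, a log2 fold change of -0.77 ± 0.171. ENSBTAG00000008633 went from 38.6 ± 3.90 to 16.9 ± 4.49 CPM, a log2 fold change of -1.17 ± 0.260. For each of these 4 genes, all 3 Cryotop libraries lay on one side of all 3 CTR libraries. Their adjusted p was 0.434 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so none passed the threshold of 0.05. By DESeq2 the adjusted p-values were 0.0189, 0.0256, 0.0256 and 0.0231, and all 4 also passed by edgeR without a filter on low counts. In that unfiltered fit each gene's own spread no longer counted. With the replicate number as a block, edgeR passed only ENSBTAG00000015792 of the 4, with an adjusted p of 0.0160. In Nanuq the 4 genes measured 84.9 ± 32.7, 92.7 ± 12.7, 183 ± 43.6 and 29.6 ± 3.51 CPM.

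Over the 14005 genes, edgeR called 0 between Cryotop and CTR at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1037 genes, 391 higher and 646 lower in Cryotop, where evenly spread p-values would give 700.3. The other 9 splits of the 6 libraries into groups of 3 gave a median of 660 and at most 934. DESeq2 called 52 genes, 23 higher and 29 lower, and limma voom called 0. Of the 52, 38 averaged 50 CPM or more, and their absolute log2 fold changes ran from 0.40 to 1.76 with a median of 0.71. Fitted without a filter on low counts, edgeR called 58 genes. Leaving out 1 library at a time moved the 1037 to between 780 (without CTR replicate 2) and 1629 (without Cryotop replicate 2). Without Cryotop replicate 2 edgeR called 8 genes, all lower in Cryotop. The Cryotop libraries left in that fit are replicates 1 and 3, the pools with fewer detected genes, which also enter the 391 and 646 above. Without Cryotop replicate 1, without CTR replicate 3, or with the replicate number as a block, edgeR called 1. The fitted change was bounded within 2-fold in either direction (95% interval) for 96.4% of the genes at 50 CPM or more, 49.5% of those at 5 to 50 CPM and 0 of those under 5 CPM. Groups that did not overlap were seen for 11.9% of genes and 13.7% of those at 50 CPM or more, where chance gives 10%.

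The comparison of Nanuq with CTR asks the same of the other device. The smallest p-value belonged to ENSBTAG00000043571, an abundant transcript at 719 ± 143 CPM in CTR and 1222 ± 124 CPM in Nanuq (mean ± SD, n = 3), a log2 fold change of 0.77 ± 0.149 (SE). ENSBTAG00000014529 measured 55.9 ± 5.16 CPM in CTR and 97.1 ± 4.01 CPM in Nanuq, a log2 fold change of 0.80 ± 0.167. ENSBTAG00000013358 was lower, at 397 ± 51.9 CPM in CTR and 251 ± 32.3 CPM in Nanuq, a log2 fold change of -0.66 ± 0.142. For ENSBTAG00000038488 the levels were 497 ± 36.5 and 320 ± 48.8 CPM, a log2 fold change of -0.64 ± 0.148. All 3 Nanuq libraries lay outside the range of CTR for each of the 4. The adjusted p was 0.698 for each by edgeR, and 0.00262, 0.00144, 0.00262 and 0.0145 by DESeq2. All 4 passed by edgeR without a filter on low counts, where each gene's own spread no longer counted. In Cryotop the same genes measured 1113 ± 118, 86.9 ± 10.1, 273 ± 6.14 and 326 ± 47.8 CPM. The genes were chosen against the same CTR libraries, so their side of CTR in Cryotop is not independent evidence.

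Between Nanuq and CTR edgeR called 0 of 14005 genes. At an unadjusted p under 0.05 there were 598 genes, 292 higher and 306 lower in Nanuq, where evenly spread p-values would give 700.3. The other 9 splits of these 6 libraries gave a median of 320 and at most 645. Of the 4031 genes at 50 CPM or more, 342 (8.48%) lay under 0.05. DESeq2 called 25 genes, 18 higher and 7 lower, of which 24 averaged 50 CPM or more. limma voom called 0, with a smallest adjusted p of 0.0678. edgeR called 19 without a filter on low counts, and 1 without Cryotop replicate 3. That library enters this comparison through the shared estimate of spread, the filter and the scaling. Weighting each library by its quality, an alternative added after seeing the data, gave 5 by limma voom, all among the 25. Among genes at 50 CPM or more, 98.0% had a change bounded within 2-fold. Groups did not overlap for 12.7% of genes and 16.1% of those at 50 CPM or more, where chance gives 10%.

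Nanuq against Cryotop compares the devices directly. ENSBTAG00000016359 measured 19.9 ± 1.53 CPM in Nanuq and 6.59 ± 1.71 CPM in Cryotop (mean ± SD, n = 3), a log2 fold change of 1.58 ± 0.355 (SE), with CTR between them at 13 ± 2.31 CPM. ENSBTAG00000001825 measured 35.8 ± 1.31 CPM in Nanuq and 14.2 ± 6.92 CPM in Cryotop, a log2 fold change of 1.29 ± 0.318. In the other direction, ENSBTAG00000030933 measured 8.19 ± 1.38 CPM in Nanuq and 22.5 ± 3.14 CPM in Cryotop, a log2 fold change of -1.45 ± 0.375. ENSBTAG00000003025 measured 12.3 ± 1.82 CPM in Nanuq and 25.4 ± 1.23 CPM in Cryotop, a log2 fold change of -1.04 ± 0.279. The libraries of the groups did not overlap for these genes, and none passed the threshold: the adjusted p was 1 for all 4 by edgeR and between 0.0880 and 0.234 by DESeq2. Without a filter on low counts ENSBTAG00000001825 passed by edgeR, with an adjusted p of 0.0340. Its own spread no longer counted in that fit, and its adjusted p ran up to 1 over the other alternatives.

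**Figure D3:**
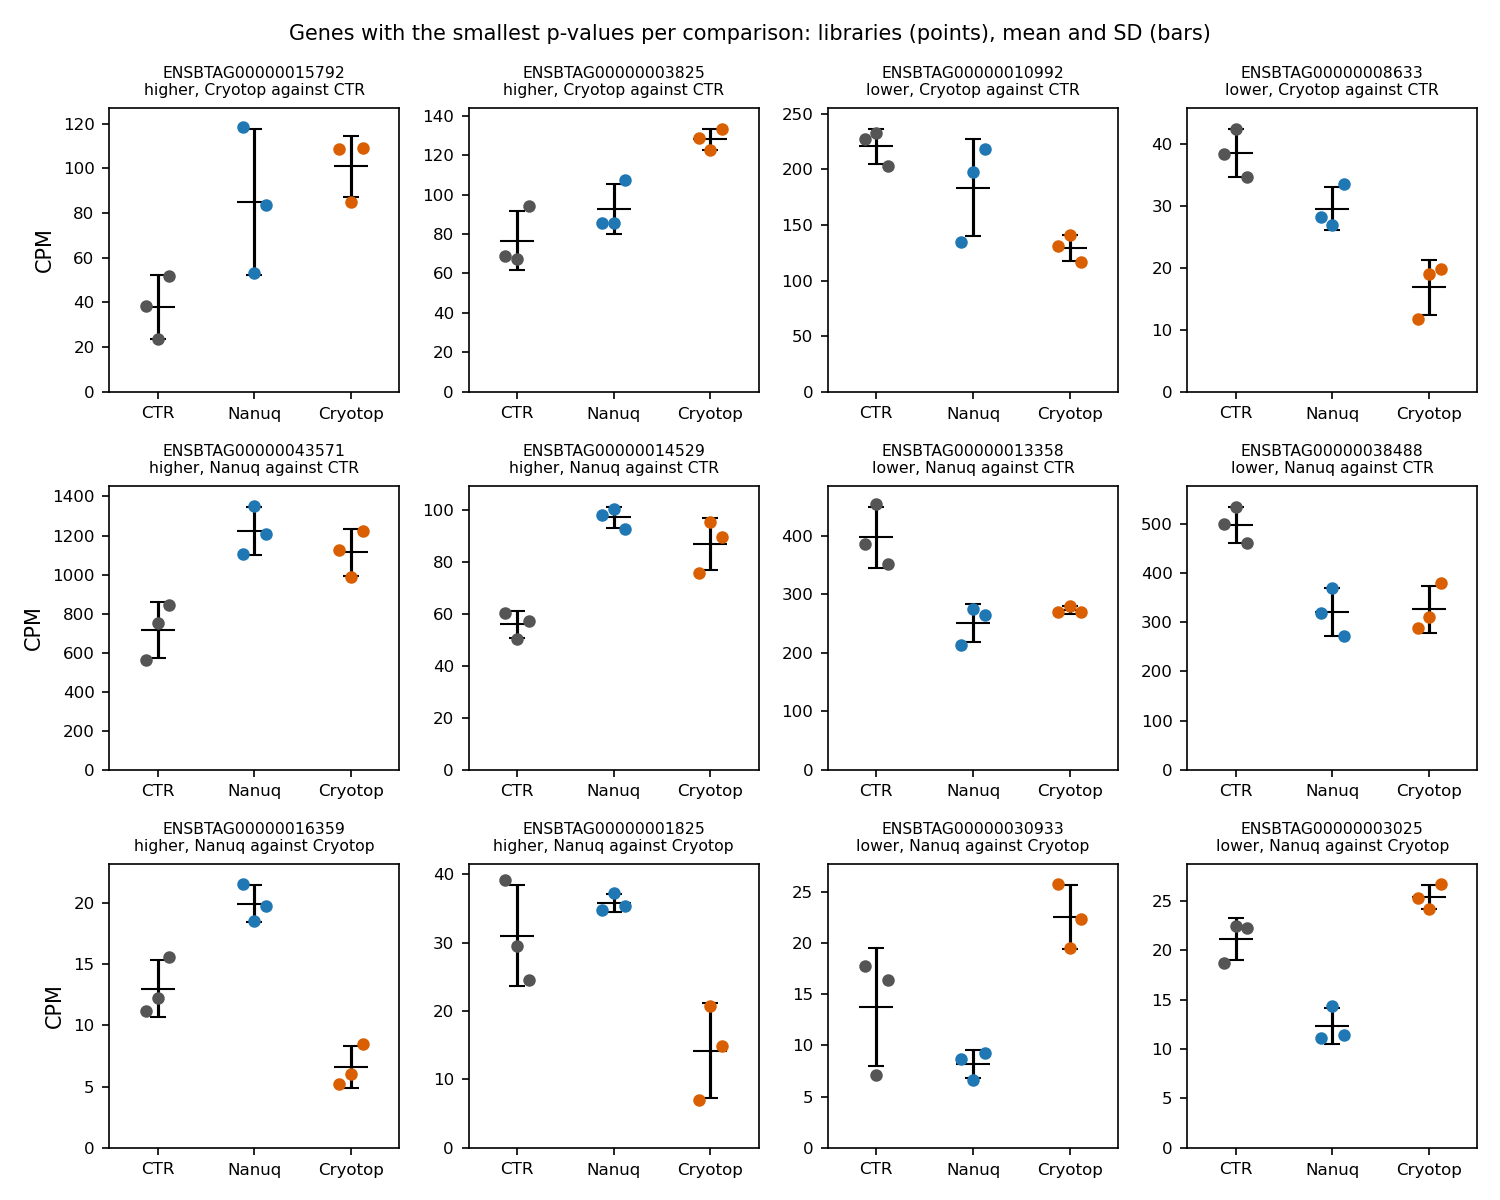
CPM of the 12 genes named for the 3 comparisons, each panel a gene with its identifier, direction and comparison; points are libraries, horizontal marks are group means and bars are SD (n = 3). In each panel the 2 groups compared do not overlap.

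Between the devices edgeR, DESeq2 and limma voom each called 0 genes. At an unadjusted p under 0.05 there were 569 genes, 349 higher and 220 lower in Nanuq, where evenly spread p-values would give 700.3 and the other 9 splits of the 6 libraries gave a median of 490 and at most 928. With 1 library left out at a time, the 569 moved to between 332 (without Nanuq replicate 2) and 1284 (without Cryotop replicate 2). The Cryotop libraries left without replicate 2 are the pools with fewer detected genes. Those pools also enter the 349 and 220 above. edgeR called 7 genes without a filter on low counts, and 1 without Cryotop replicate 1 or without Cryotop replicate 2. For 98.6% of genes at 50 CPM or more the difference between devices was bounded within 2-fold. That share was 52.8% at 5 to 50 CPM and 0 under 5 CPM. Groups did not overlap for 10.2% of genes and 11.4% of those at 50 CPM or more, against 10% by chance.

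With Nanuq and Cryotop averaged and set against CTR, the 6 cooled pools are compared with the 3 controls. edgeR called 0 genes, with a smallest adjusted p of 0.328, and limma voom called 0, with a smallest adjusted p of 0.0504. At an unadjusted p under 0.05 there were 881 genes, 358 higher and 523 lower in the cooled groups, and 465 of them averaged 50 CPM or more. DESeq2 called 55 genes, 32 higher and 23 lower, 49 of them at 50 CPM or more, with absolute log2 fold changes of 0.33 to 1.29 and a median of 0.54. Without a filter on low counts edgeR called 56, and limma voom with library weights called 1. With the replicate number as a block, edgeR called 1 gene, ENSBTAG00000015792, with an adjusted p of 0.0176. The test for any difference among the 3 groups gave 0 genes by edgeR, 704 at an unadjusted p under 0.05, 42 by DESeq2 and 0 by limma voom. edgeR gave 62 for that test without a filter on low counts and 1 without Cryotop replicate 1, and limma voom with library weights gave 2. Leaving out 1 library at a time moved edgeR's 704 to between 524 (without Nanuq replicate 2) and 1208 (without Cryotop replicate 2).

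Whether both devices moved the same genes was compared through the 2 sets of changes against CTR. edgeR called 0 genes in either set, so none were shared (598 and 1037 genes lay at an unadjusted p under 0.05). DESeq2 called 10 genes in both, 7 higher and 3 lower, all in the same direction. Among the 5642 genes with an adjusted p in both, 25 were called for Nanuq and 44 for Cryotop, and independent lists of that kind would share 0.0936 genes in the same direction. Simulated groups that did not differ from the same controls shared 1 gene on average and at most 3 over 20 simulations, but their lists were shorter, at 11.6 calls for Nanuq and 6.3 for Cryotop on average. DESeq2 was run on the 14005 tested genes in simulation and on the whole table for the real lists. Among genes at 50 CPM or more the log2 fold changes of Nanuq and Cryotop had a correlation across genes of 0.650 and a covariance of 0.0358. Unchanged groups simulated against the shared controls gave 0.498 and 0.0211 ± 0.000806 (SD of the covariance over 20 simulations). The same sign was seen for 71.6% of these genes, against 66.5% in simulation. The simulation drew each gene on its own, so its SD leaves out shifts common to many genes of a pool. Over 84 choices of controls among the real libraries, the covariance less the sampling variance of the control mean averaged -0.0155 to 0.0179. With CTR as the controls it averaged 0.0147. Over all 14005 genes the covariance was 0.255, and simulation gave 0.264. Less the sampling variance of the CTR mean, 0.234, that covariance left an excess of 0.0211. The 2 measures thus differ in sign over all genes, and a shared shift there was not settled. The 3 CTR libraries were not split between the devices, so part of any excess may come from the shared controls.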

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

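The tests of gene detection below were chosen only after the numbers of detected genes had been seen. The 6 cooled libraries were searched for single libraries far from the others, over 19 library measures and gene levels, and 4 stood apart. Chance alone gives about 1 in 20 for independent values from a single normal group. The values searched are related to each other and include the genes named above, chosen for group differences. The 4 therefore cannot be weighed against that share.

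In 3 of the 4 the library was Cryotop replicate 1. Its total count of 3970666 (3.97M) lay below the next lowest, 16343398. Its leading gene held 4.56% of counts, against at most 1.60% in the other 5, and its 100 most abundant genes held 27.0%, against at most 24.8%. The fourth was the level of ENSBTAG00000013358 in Nanuq replicate 1, 214 CPM, where the nearest of the cooled libraries had 264 CPM.

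Fewer genes were detected in Cryotop replicates 1 and 3 than in the other 7 libraries. Depth is argued against: at the smallest library's total, replicates 1 and 3 would show 12104 and 12409 genes, where the lowest of the other 7 libraries would show 13577. A response of the Cryotop group stays open, but it was not seen in all its pools. Cryotop replicate 2 had 14664 genes at that total, above the mean of the 6 libraries of the other groups, 14094 ± 510.4 (SD). Over all 3 Cryotop libraries the mean was 13059 ± 1399 (SD, n = 3), with a one-sided exact permutation p of 0.0714. That p rests on replicates 1 and 3, whose low numbers prompted the test, so it cannot decide whether the group responded. Loss of transcripts in single libraries, as when little RNA enters a library, stays open too: among 9862 genes averaging 5 CPM or more in the other 7 libraries, 124 and 67 were at 0 and 9 were at 0 in both. Draws matched on expression shared 6.24 on average, and 9 or more with a permutation p of 0.156, so the missing genes may be largely different ones in each pool. Embryos that differed between pools were not tested.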

How the results depend on the processing

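Tests with library weights, and without both Cryotop replicates 1 and 3, were added after seeing the data. edgeR called 0 genes in all 5 comparisons. Over 117 combinations of comparison and alternative, 94 also gave 0 and 23 gave more. In the order Cryotop against CTR, Nanuq against CTR, Nanuq against Cryotop, both cooled groups against CTR and any difference, dropping the filter gave 58, 19, 7, 56 and 62 genes. The 58 and the 56 were all genes tested with the filter. Dropping it made the estimated prior degrees of freedom infinite (median 12.9 with the filter), so that each gene's own spread no longer counted. The smallest p-value of that fit for Cryotop against CTR belonged to ENSBTAG00000052217. This gene held 4.56% of counts in Cryotop replicate 1, and 0.010% and 0.0400% in Cryotop replicates 2 and 3. DESeq2 gave 52, 25, 0, 55 and 42, and 10 genes shared by both comparisons with CTR, where edgeR shared 0. Why it called more was not settled.

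With the replicate number as a block, edgeR gave 1 gene for Cryotop against CTR, 1 for both cooled groups and 0 for the others. The 1 gene was ENSBTAG00000015792 in each, with adjusted p-values of 0.0160 and 0.0176; for Cryotop against CTR its adjusted p ran from 2.18e-08 to 1 over all alternatives. Same-numbered libraries of different groups deviated from their group means with correlations of -0.0118 to 0.0434. For libraries with other numbers these were -0.0387 to 0.0263. The ranges overlap and what the numbers mark is not given, so whether they pair libraries was not settled. Leaving out each library in turn gave 0 to 8 genes for Cryotop against CTR (8 without Cryotop replicate 2, 1 without Cryotop replicate 1 or CTR replicate 3). It gave 0 to 1 for Nanuq against CTR (1 without Cryotop replicate 3), for Nanuq against Cryotop (1 without Cryotop replicate 1 or 2) and for any difference (1 without Cryotop replicate 1), and 0 for both cooled groups. limma voom with library weights gave 5 for Nanuq against CTR, 1 for both cooled groups and 2 for any difference. Without both Cryotop replicates 1 and 3, which leaves 1 Cryotop library assumed to vary like the other groups, edgeR gave 1 for Nanuq against CTR and 1 for any difference. The cause was not tested for these changes.

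The 12 named genes kept their direction in all 259 combinations of gene and alternative, and 19 passed the threshold, 8 of them by DESeq2. These genes were chosen for small p-values in the same libraries, with groups that do not overlap, so a kept direction is not independent evidence. The separation of the groups gave p-values of 0.0786 to 0.214 over its alternatives. Gene list tests and the sex covariate were not run, because identifiers had no symbols. Spread and depth limit genes under 5 CPM most.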

Other observations

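The tests of DESeq2's calls and of the shift common to both cooled groups were set down before their results were seen, although both patterns had been noticed in these data. The median SD of log2 CPM between replicates was 0.211 in Cryotop, 0.189 in CTR and 0.143 in Nanuq among genes at 50 CPM or more. It was 0.437, 0.310 and 0.283 at 5 to 50 CPM, and 2.00, 1.04 and 0.957 under 5 CPM. The Cryotop values include replicate 1, with 3970666 counts against 16343398 or more in the other 8 libraries, and replicate 3, which the second principal component set apart.

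DESeq2 called 55 genes between both cooled groups and CTR, where edgeR called 0 and 881 lay at an unadjusted p under 0.05. Over all 84 choices of 3 libraries as controls, 4 gave as many DESeq2 calls, the real one included, a share under 5%, and the highest other gave 88. For each choice but the real one, the remaining libraries were divided into Nanuq and Cryotop by a single random draw. Another draw could move that share across 5%. The 3 other choices, with 88, 81 and 74 calls, each held Cryotop replicates 1 and 3, while the 4 further choices that held both gave 27, 26, 9 and 0. A spread estimate inflated by thinly expressed genes is argued against as the reason for edgeR's 0, since edgeR fitted to genes of 50 CPM or more alone also called 0. Its smallest adjusted p was then 0.0926. In the full fit, with adjustment over genes of that class alone, it was 0.0944, so leaving thin genes out of the fit hardly moved it. What stays open is a real but small difference and DESeq2's own error: when no gene differed in simulation it called on average 6.3 genes for Cryotop against CTR and 11.6 for Nanuq against CTR, at most 14 and 24, against the 52 and 25 observed. The simulation held only the 14005 tested genes, with the same dispersions in all 3 groups. The 52 and 25 came from the whole table, so the 2 sets of counts are not strictly alike.

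A hypothesis is that abundant transcripts of hatched blastocysts differ from CTR in the same way with either device. Over the 4031 genes at 50 CPM or more, the covariance of both sets of log2 fold changes exceeded the sampling variance of the CTR mean by 0.0148, a shared shift with an SD of 0.12 on the log2 scale. Only 17 of 840 arrangements of the libraries gave as large an excess (7 of them with the real controls), with 0.0203 the highest other, which argues against the shared controls alone; averaged per set of controls, 2 of 84 sets did, the other being CTR replicate 2 with Nanuq replicates 2 and 3. The shallow Cryotop replicate 1 is argued against as the source, since without it the excess was 0.0181. The excess rests in part on CTR replicate 1, without which it was 0.0065, and a difference between the CTR pools and the rest that is unrelated to cooling could give the same pattern.

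For both cooled groups against CTR, 6 of 84 splits gave as many genes at an unadjusted p under 0.05 by edgeR as the real 881, the highest of the others 1164, so chance cannot be excluded for that count. These splits, too, divided the libraries not taken as controls by a single random draw. Splits say nothing of edgeR's counts of 0, which any split reaches: 84 of 84 did for both cooled groups (the highest other 1), 100 of 100 drawn for any difference (1), and 10 of 10 each for Cryotop against CTR (0), Nanuq against CTR (0) and Nanuq against Cryotop (1). The 10 splits of a pair of groups are also too few for a share under 5%. DESeq2's 52 for Cryotop against CTR compared with at most 33 in the other splits of that pair, and its 25 for Nanuq against CTR with at most 26.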
